A study of Sus scrofa with 12 samples.

How the data were processed

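Ovarian total RNA from 6 ES and 6 NES gilts was examined, with group and replicate number taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, depleted of ribosomal RNA and made into strand-specific libraries by the dUTP method. The submitters' processing notes name cutadapt, FastQC, HISAT2, TopHat and the pig build Sscrofa11.1, with no version. The counting program, its strand setting and the annotation are not given in the sources used here.

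The authors deposited a table of 29150 loci with a raw count and an FPKM value per library, per the file headers. Of these loci, 24887 carry an assembled-locus identifier (MSTRG) and 4263 an Ensembl identifier. The deposited FPKM values are normalised for length and library size by the authors. The count columns hold whole numbers that sum to 58140547 to 68961955 per library, and every per-sample column was used. Loci without a gene name held 7.99 to 11.3% of the counts, and the 10 most abundant loci 5.26 to 8.70%. No locus lies on a mitochondrial chromosome, so the list of mitochondrially encoded genes had no measured member.

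Gene symbols came from the table. Bare Ensembl identifiers were looked up in a name table (922 of 5429 matched), and 333 further loci, HSD3B1 and MKI67 among them, were named from a RefSeq gene of the same build with a reciprocal overlap of at least 0.5. In a test on named loci, 1172 of 1205 matched loci (97.3%) received their own symbol. Where a symbol stood on several loci (3199 symbols), the locus with the highest mean FPKM stood for it. Antisense, overlapping and joined loci, and near-identical copies such as histone genes, can share reads, so their values are less certain. Of 655 genes in the fixed lists, 459 had a locus of their own past the expression filter and 60 lay only in a joined locus. List members in joined loci were left out.

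The test fixed before the data were examined was limma on log2(FPKM + 0.5), because only FPKM was foreseen. As the table also holds counts, the main test became edgeR's quasi-likelihood test on the counts, with TMM factors and no covariate, on 20421 loci with a mean FPKM of at least 0.5. The limma fit is an alternative. Adjusted p-values are Benjamini-Hochberg values over all tested loci, called under 0.05. The SE of a log2 difference is the difference divided by the square root of its F statistic. Group values are CPM with TMM factors, as mean ± SD over 6 libraries. Each library comes from a separate gilt. The labels do not say that the title numbers mark litters, and they were not used as pairs. SHOC2 and ASH1L were tested by an exact two-sided permutation test of log2(FPKM + 0.5), with a 95% interval of the difference of means from Welch's approximation.

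The 27 gene lists, of ovarian cell types, steroid and cholesterol pathways, hormone response, cell cycle and stress, were fixed before the data were examined. The 25 with at least 5 measured members were tested with limma's camera on the edgeR fit (preset correlation 0.01), again with an estimated correlation, and with fry, which tests whether a list moves in a direction on balance. Named genes followed a fixed rule. It took the title genes SHOC2 and ASH1L, 12 genes of steroid synthesis and ovarian function, the 8 largest called changes in each direction with a mean FPKM of at least 1 and a symbol in the table itself, and up to 4 members with the smallest p-values of each list that passed camera or had a called member. Genes outside the rule are said to be chosen after their values were seen.

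On counts simulated from these libraries, with 50 changed loci per fold among 20421, edgeR recovered 3 at 1.5-fold, 25 at 2-fold, 40 at 3-fold and 48 at 4-fold with 2 false calls. DESeq2 recovered 12, 41, 47 and 49 with 47 false calls, and limma 3, 24, 40 and 45 with 6. Camera called the changed list and 0 of 26 unchanged lists there, while on the measured libraries it called 3 to 17 lists in each of the 99 other divisions described below. The simulation drew each locus independently, with the same dispersion in both groups, and gave limma scaled CPM instead of FPKM. It leaves out the correlation between genes (estimated at 0.69 in the cell cycle list) and the wider spread in ES. Its false calls thus do not carry over to the measured libraries.

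Alternatives fixed beforehand were pseudocounts of 0.1 and 1, TPM, quantile and median-of-ratios scaling, no filter and a minimum mean FPKM of 1, the replicate number as a block, each library left out, robust and weighted limma, and a rank-sum test per locus. The edgeR fit, its robust form, DESeq2, the fit without ES3 and ES6 together and tests on the table's GO terms and histone loci were added after the data were seen. The counts of calls were repeated on 100 divisions of the 12 libraries into 6 and 6, the real one among them. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. No genome sequence was used here.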

Results

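Gene-level RNA was measured in the left ovaries of 12 gilts, young female pigs (Sus scrofa) of a French Yorkshire line. The ES group holds 6 gilts with regular estrus, killed during the third estrus. The NES group holds 6 full sisters in which no estrus was recorded. Whole ovaries were used, so follicles, luteal tissue, stroma, vessels, immune cells and oocytes all contribute to a value. Libraries of total RNA depleted of ribosomal RNA held 58140547 to 68961955 counts over annotated and assembled loci. Levels are given as counts scaled to library size (CPM). A locus with no count in a library had an upper limit of 0.0435 to 0.0516 CPM, for counting error only. The table gives 29150 loci on the pig build Sscrofa11.1, and 20421 of them had a mean FPKM of at least 0.5 and were tested.

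The main comparison asks how ovaries at estrus differ from those of gilts without recorded estrus. Of the cell cycle genes 14 fell in the ES ovaries, as did the hedgehog genes IHH, HHIP and GLI1. TOP2A (MSTRG.4172, chromosome 12, 22001436 to 22031112), the topoisomerase that untangles replicated DNA, averaged 21.5 ± 9.64 CPM in ES and 95.2 ± 49.8 CPM in NES (SD, n = 6 each). IHH (MSTRG.9229, chromosome 15, 121080072 to 121090836), the hedgehog ligand that granulosa cells secrete, averaged 8.68 ± 5.44 CPM in ES and 70.1 ± 41.2 CPM in NES. CD44 (MSTRG.11826, chromosome 2, 25788693 to 25884980), the cell surface receptor for hyaluronan, rose most among called genes with a mean FPKM of at least 1, from 11.2 ± 4.19 CPM in NES to 65.0 ± 33.7 CPM in ES. In all, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 193 loci, 31 higher and 162 lower in ES.

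Of the 33 measured cell cycle genes, 14 fell in ES over all loci tested and 31 when adjusted over the list alone, with a median log2 difference of -1.39. TOP2A changed by -2.15 ± 0.38 (log2, SE; adjusted p = 0.0371), and TTK, a spindle checkpoint kinase, by -2.03 ± 0.33 (adjusted p = 0.0342). CENPF and BIRC5, proteins of the dividing chromosome, changed by -1.78 ± 0.28 and -1.62 ± 0.25 (adjusted p = 0.0337 for both). CENPE, a motor protein of the kinetochore, changed by -1.66 ± 0.27 (adjusted p = 0.0349). TTK was below every NES library in 5 of 6 ES libraries, and CENPF, BIRC5 and CENPE in 6 of 6. Among 29 alternative fits, 16 called TOP2A, 17 TTK and 18 each CENPF and BIRC5, and 14 of 28 called CENPE. The list passed camera, limma's competitive set test (adjusted p = 7.26e-47 with a preset correlation). It had an adjusted p of 0.0894 with an estimated correlation, and the directional fry test gave 0.0334. Other genes with large falls were PCLAF, a partner of the replication clamp (-2.20), CCNB1, the mitotic cyclin B1 (-2.06), CENPA, the centromeric histone (-2.02), and FBXO5, an inhibitor of the anaphase-promoting complex (-2.02). The FBXO5 value is for a short strandless stretch (MSTRG.127, chromosome 1, 13474878 to 13475235). The longer FBXO5 (MSTRG.126) locus, looked up after the values were seen, changed by -1.69.

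IHH fell by 3.01 ± 0.61 on the log2 scale (adjusted p = 0.0420) and was lower in all 6 ES libraries than in any NES library. The same held for HHIP, the hedgehog-binding protein, at 8.15 ± 5.14 CPM in ES and 42.2 ± 13.2 CPM in NES (log2 -2.37 ± 0.40, adjusted p = 0.0358). GLI1, the transcription factor at the end of the hedgehog pathway, fell from 18.6 ± 5.21 CPM in NES to 4.86 ± 2.05 CPM in ES (log2 -1.94 ± 0.30, adjusted p = 0.0337). IHH was called in 16 of 29 alternative fits, and HHIP and GLI1 in 18 each. The hedgehog receptor PTCH1 had a log2 difference of -1.65 (adjusted p = 0.0564) at the short locus with its highest FPKM. At the long PTCH1 (MSTRG.2640) locus, chosen after its value was seen, it fell from 515 ± 170.0 CPM in NES to 142 ± 70.6 CPM in ES (log2 -1.86, adjusted p = 0.0387).

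CD44 rose with a log2 change of 2.54 ± 0.35 (adjusted p = 0.0337). PTGER4, a receptor for prostaglandin E, rose from 3.60 ± 0.78 to 9.64 ± 3.33 CPM (log2 1.42 ± 0.23, adjusted p = 0.0337). CDKN1A, the cyclin-dependent kinase inhibitor p21, rose from 10.6 ± 1.79 to 25.3 ± 11.4 CPM (log2 1.25 ± 0.27, adjusted p = 0.0487). With each symbol taken at its locus of highest FPKM and a mean FPKM of at least 1, the rest of the 8 largest rises were PLAC8 (1.31), the monoamine oxidase MAOB (1.13), the transmembrane protein TMEM52 (1.09), FRMD6 (1.08) and the glycosyltransferase B3GNT2 (0.96). CD44, PTGER4, TMEM52, FRMD6 and B3GNT2 were higher in all 6 ES libraries than in any NES library. Of 29 alternative fits, 18 called CD44, 17 PTGER4, 14 TMEM52, 12 B3GNT2, 10 each CDKN1A and MAOB, 8 PLAC8 and 7 FRMD6. Of the 23 hormone and gonadotrophin receptors only PTGER4 rose, and of the 17 apoptosis genes only CDKN1A; adjusted over the lists alone, 3 receptors rose, 1 fell and 1 apoptosis gene rose. Neither list passed camera (adjusted p = 0.379 and 0.144). Among their other members with small p-values, ESR2, an estrogen receptor, had a log2 difference of -0.98, the apoptosis ligand TNFSF10 0.60, the transcription factor FOXO3 0.25 and BBC3 0.52 (0.17 without ES3).

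**Figure D1:**
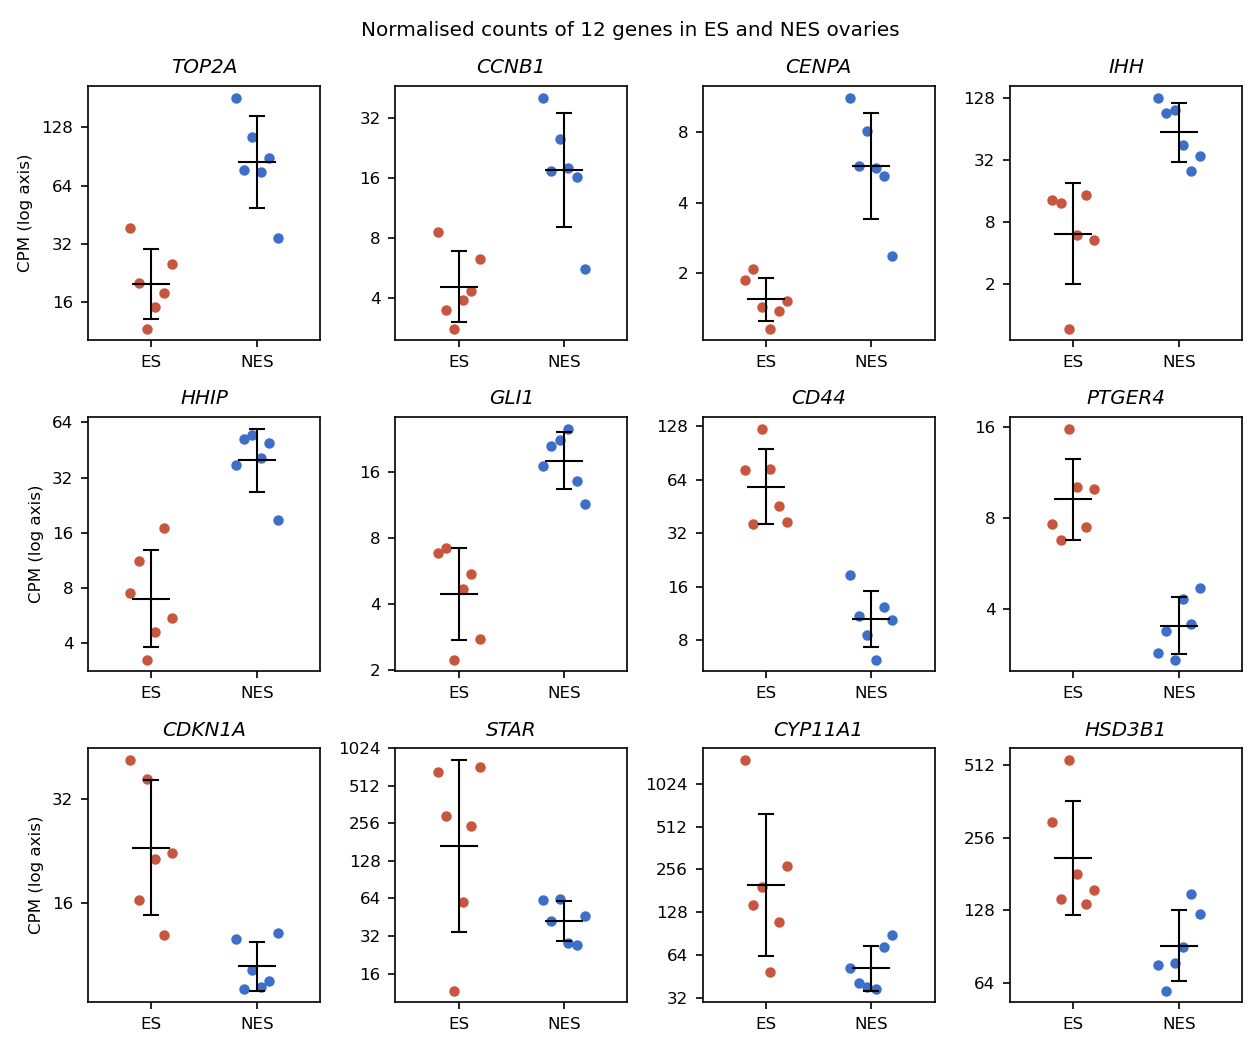
Normalised counts (CPM, log axis) of 12 genes in the 6 ES and 6 NES libraries. Points are libraries, and bars give the mean and SD of the log2 values. The cell cycle and hedgehog genes sit lower in ES (TOP2A 21.5 against 95.2 CPM on average), CD44, PTGER4 and CDKN1A sit higher, and STAR and CYP11A1 spread widely within ES.

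Of the 21 measured genes of steroid hormone synthesis, 19 had positive log2 differences, and none passed the test over all loci. STAR, which carries cholesterol into mitochondria, averaged 331 ± 299 CPM in ES and 45.0 ± 15.8 CPM in NES (log2 2.88 ± 0.74, adjusted p = 0.0844). CYP11A1, which makes pregnenolone from cholesterol, averaged 379.9 ± 561 and 54.9 ± 21.4 CPM (log2 2.79 ± 0.73, adjusted p = 0.0894). HSD3B1, which makes progesterone, averaged 242 ± 157 and 96.1 ± 33.8 CPM (log2 1.33, adjusted p = 0.0979). These 3 rose when adjusted over the list alone. CYB5A had a log2 difference of 1.25 (adjusted p = 0.182), the androgen-forming CYP17A1 2.00 (0.383) and the aromatase CYP19A1 1.43 (0.455). The list had a median log2 difference of 0.51 (0.29 with the replicate block) and passed camera (adjusted p = 0.00406). Its camera adjusted p was 0.441 with an estimated correlation and 0.102 without ES1. Without ES1 the log2 difference of CYP11A1 was 1.48, and without ES6 that of CYP19A1 was 0.50. The direction of CYP17A1 turned with limma on TPM (-0.034).

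The 13 luteal cell markers had a median log2 difference of 1.01 (0.66 with the replicate block). Their adjusted p was 4.08e-04 with camera, 0.0894 with camera and an estimated correlation, and 0.0336 with fry. None passed over all loci, while 6 rose and 1 fell adjusted over the list alone. PTGFR, the receptor for the luteolytic prostaglandin, averaged 106 ± 46.4 CPM in ES and 36.3 ± 15.0 CPM in NES (log2 1.54, adjusted p = 0.0564), and was higher in 6 of 6 ES libraries than in any NES library. The 22 genes of cholesterol synthesis and uptake all had positive log2 differences (median log2 0.60, camera adjusted p = 0.00662, 0.487 as adjusted p with an estimated correlation), and none was called in either way of adjusting. Members with small p-values included HMGCS1 (1.15), SCARB1 (1.01) and SC5D (0.60), which without ES1 stood at 0.69, 0.34 and 0.39. Without ES1 the list's median was 0.19 (adjusted p = 0.370), and without ES6 its adjusted p was 0.0541. Markers of the ovulatory response to the LH surge had a median log2 difference of 1.03 over 20 genes (0.65 without ES1, 0.53 with the replicate block). The camera adjusted p was 1.96e-04, and 0.441 with an estimated correlation. CD44 rose, and 6 rose adjusted over the list alone. The epidermal growth factor family member AREG (log2 6.82, adjusted p = 0.0932), PTGS2, which makes prostaglandin precursors (4.55, 0.136), and the transcription factor CEBPB (1.02, 0.158) did not pass over all loci. AREG had 1.92 without ES1, and PTGS2 0.42 without ES4.

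Of the gonadotrophin and steroid receptors fixed for naming, the FSH receptor FSHR averaged 30.2 ± 20.3 CPM in ES and 68.1 ± 23.1 CPM in NES (log2 -1.17, adjusted p = 0.216). The LH receptor LHCGR had a log2 difference of 0.54 (adjusted p = 0.697), the progesterone receptor PGR 1.76 (0.300) and the estrogen receptor ESR1 -0.49 (0.462). The inhibin subunit gene INHA averaged 1372 ± 1345 CPM in ES and 481 ± 293 CPM in NES (log2 1.51, adjusted p = 0.412). Without ES1 the log2 difference of PGR was 0.091 and that of INHA 0.95, and without ES3 that of ESR1 was -0.32. The direction of LHCGR turned without ES6 (-0.18) and in every limma fit except the weighted fit (-0.22 to -0.032). AMH lay in a locus joined with SF3A2 (MSTRG.12482), whose log2 difference of -0.56 (adjusted p = 0.194) cannot be given to AMH alone.

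Follicle cell markers moved in both directions. Of the 19 granulosa markers IHH fell, and adjusted over the list alone 3 fell and 1 rose. The members beside IHH with the smallest p-values were the activin-binding protein FST (-2.03), the inhibin subunit INHBB (-1.82) and the BMP receptor BMPR1B (2.77, and 0.75 without ES1). The granulosa median was 0.16 (-0.21 without ES6, -0.17 with limma on TPM, -0.051 after quantile and -0.017 after median-of-ratios scaling of FPKM) while the mean was -0.02 and camera placed the list lower (adjusted p = 0.0489, 0.487 as adjusted p with an estimated correlation), so the median differs in sign from the mean and the test. Its call held in 8 of 26 alternative fits and was lost, among others, without any of ES2, ES3, ES4, ES5, NES1 or NES3 (adjusted p = 0.0660 to 0.228). Of the 14 theca markers HHIP and GLI1 fell, and adjusted over the list alone 3 fell and 4 rose, the rises being STAR, CYP11A1, HSD3B1 and the lipid carrier APOE (1437 CPM in ES3 and at most 137 CPM in any other library). That list did not pass camera (adjusted p = 0.139), which placed it lower although its median was 0.55 (0.042 without ES6, -0.13 with limma on TPM), nor did the 13 oocyte markers (median -0.24, and -0.40 to -0.14 with a library left out; adjusted p = 0.0817, with a call in 3 of 26 alternative fits).

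Most markers of other cell types had positive log2 differences. The 7 markers of surface and ductal epithelium had a median log2 difference of 2.04, the 16 macrophage and monocyte markers 1.27 and the 8 lymphocyte markers 0.87 (camera adjusted p = 0.00205, 0.00790 and 0.00170; 0.441, 0.496 and 0.441 as adjusted p with an estimated correlation). No member passed over all loci; adjusted over the lists alone 5 epithelial, 0 macrophage and 4 lymphocyte markers rose. The epithelial genes CLDN4, CDH1, UPK3B and FOXJ1 had log2 differences of 4.16, 1.89, 2.04 and 6.91, and the macrophage genes LYZ, CD86, LAPTM5 and TYROBP 4.65, 1.25, 1.45 and 2.13. The lymphocyte genes CD4, ZAP70, CCL5 and IL7R had 2.21, 0.73, 1.02 and 1.24. The CD4 value is for a short locus (MSTRG.17341, chromosome 5, 63910933 to 63911518) at low counts. It averaged 0.56 CPM in ES and 0.12 CPM in NES, with 0 in NES1. Without ES3 the macrophage median was -0.057, its call was lost (adjusted p = 0.914) and LYZ and TYROBP turned to -0.26 and -0.13, while CD86, LAPTM5 and IL7R stood at 0.41, 0.24 and 0.73. Without ES6 the epithelial median was 0.90, CLDN4 and CDH1 stood at 1.92 and 1.21, and FOXJ1 turned to -1.08. Markers that passed the expression filter through ES6, such as FOXJ1, stay in that median. With the replicate block the epithelial, macrophage and lymphocyte medians were 1.17, 0.45 and 0.77. Endothelial markers (15 genes, median 0.35), smooth muscle and pericyte markers (16, 0.33, and 0.50 without ES3) and stromal matrix genes (22, 0.24) passed camera with adjusted p = 0.00342, 0.0239 and 0.0239, each with 0.487 as adjusted p with an estimated correlation and with 0 members called in either way. SOX18, TEK, FLT4 and EMCN differed by 0.41 to 0.63, CSPG4, RGS5, TAGLN and DES by 0.60 to 1.26, and FN1, POSTN, MMP2 and ELN by 3.28, 2.43, 0.51 and 0.80. Without ES3 the values of FN1, POSTN, MMP2, TEK and FLT4 were 0.97, 0.99, 0.23, 0.25 and 0.24, without ES6 those of DES and EMCN 0.75 and 0.28, without ES4 that of CSPG4 0.59 and without ES1 that of RGS5 0.37. The smooth muscle call was lost without any of ES1, ES2, ES5, ES6, NES1, NES2 or NES3 (adjusted p = 0.0515 to 0.184) and the stromal call without any of ES1, ES5, ES6, NES1 or NES2 (0.0528 to 0.178).

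All 19 interferon response genes had positive log2 differences, with a median log2 difference of 0.74. None passed over all loci and 14 rose adjusted over the list alone, among them MX2 (1.99 ± 0.50), IFIT1 (0.84 ± 0.22) and ISG15 (1.23 ± 0.33), with adjusted p over all loci of 0.0741 to 0.0942. The list passed camera (adjusted p = 8.92e-12, 0.205 as adjusted p with an estimated correlation, fry 0.0484). The 14 complement and inflammation genes had a median of 0.41 (camera adjusted p = 0.00256, 0.272 as adjusted p with an estimated correlation) and no called member, with CXCL10 at 1.22, ICAM1 at 0.88 (0.53 without ES3), VCAM1 at 0.49 (0.31 without ES3) and C1S at 0.47. Cytosolic ribosomal protein genes lay slightly lower (31 genes, median -0.16, camera adjusted p = 6.90e-04, 0.487 as adjusted p with an estimated correlation), with RPL14, RPL7, RPL30 and RPL5 between -0.36 and -0.23 and no called member. Further lists that did not pass camera were the insulin-like growth factor system (adjusted p = 0.302), nuclear oxidative phosphorylation (0.531), immediate early and heat shock genes (0.978), hypoxia and glycolysis (0.360), histone lysine methyltransferases (0.294) and RAS-MAPK genes around SHOC2 (0.180). Adjusted over the lists alone, 1 gene rose and 2 fell in the insulin-like growth factor system. Among the histone lysine methyltransferases 1 rose and 3 fell, and no member of the other lists that did not pass moved in this way of adjusting. The red blood cell list had 2 measured genes and was not tested.

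**Figure D2:**
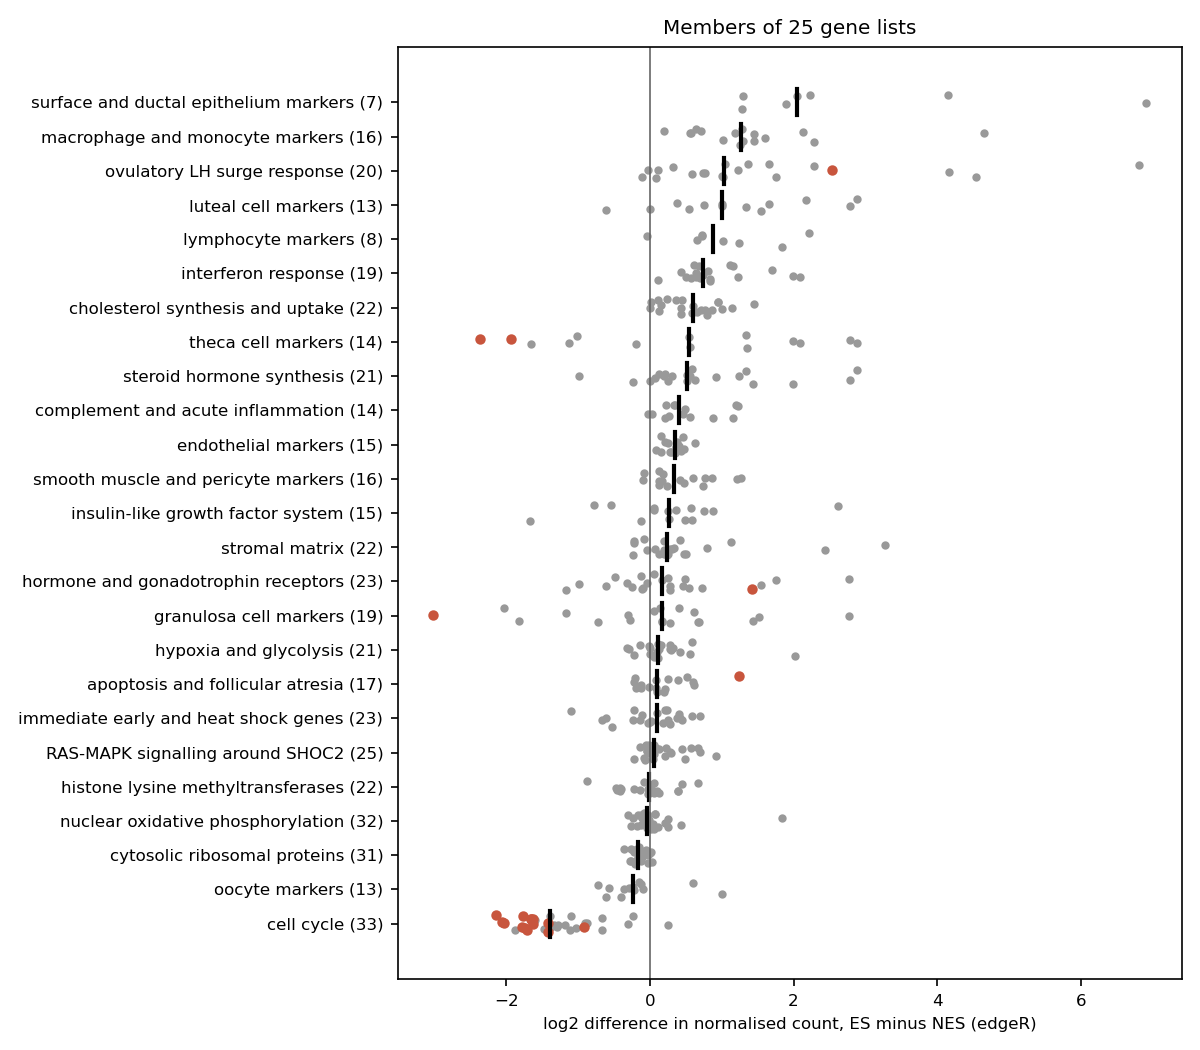
Log2 difference in normalised count (ES minus NES, edgeR) of each measured member of 25 gene lists, with the number of members in brackets. Red points passed the test over all loci, grey points did not, and black bars are list medians. The cell cycle list lies at a median of -1.39 and holds 14 of the red points.

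The 193 calls all lay between adjusted p = 0.0337 and 0.0497, and 3328 loci had an unadjusted p under 0.05 where chance gives 1021. The count was 0 without ES2, ES4, ES6, NES1, NES3, NES4 or NES5 in turn, 1 without NES2 and without ES3 and ES6 together, 68 without ES5, 85 without ES3 and 415 without NES6, with 2629 to 3811 loci at an unadjusted p under 0.05 in these fits. With the replicate number as a block, edgeR called 0 loci, with 2708 at an unadjusted p under 0.05. The labels do not say whether these numbers mark sisters. DESeq2 called 465 higher and 600 lower, and limma on TPM 7 higher and 246 lower.

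The series title concerns a circular RNA of SHOC2 and the histone methyltransferase ASH1L in granulosa cells. This raises the question of whether RNA of the 2 gene loci differs between the groups in whole ovaries. The circular RNA itself was not analysed here. In total RNA its reads can count towards SHOC2, so the values are not of linear RNA alone. SHOC2, a scaffold of RAS signalling (MSTRG.8188, chromosome 14, 121347933 to 121445756), averaged 2.65 ± 0.49 FPKM in ES and 2.58 ± 0.29 FPKM in NES (SD, n = 6 each). The difference of log2(FPKM + 0.5) was 0.023 with a 95% confidence interval of -0.22 to 0.27, within the spread between libraries (exact two-sided permutation test, p = 0.827). ASH1L (MSTRG.15873, chromosome 4, 94297619 to 94485053) averaged 7.34 ± 0.91 and 7.48 ± 0.42 FPKM, a difference of -0.032 with an interval of -0.21 to 0.14 (exact permutation p = 0.690). Adjusted over the 2 genes, both exact permutation tests had p = 0.827, and edgeR on the counts gave adjusted p = 0.646 for SHOC2 and 0.765 for ASH1L, with log2 differences of 0.13 and 0.063; the ASH1L difference thus turned, as it did without ES1 (0.0045), and that of SHOC2 turned on TPM (-0.017) and without ES3, ES4 or NES4 (-0.037 at the lowest).

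The ES libraries varied more among themselves than the NES libraries. Of the tested loci 74.5% had a larger log2 variance in ES, and the median SD was 0.413 in ES and 0.273 in NES. ES3 stood farthest from the others on the first principal component (22.0% of variance). Its 16 macrophage markers lay a median of 3.29 log2 units above the median of the other ES libraries, and all 16 were higher. In ES6 the 7 epithelial markers lay 2.96 above, all 7 higher. In ES1 the 22 genes of cholesterol synthesis and uptake lay 1.51 above (20 higher), the 19 granulosa markers 1.45 (16 higher), the 20 ovulatory response genes 1.33 (all 20 higher) and the luteal markers 0.93. NES6 had the lowest cell cycle median among the NES libraries (-1.20). The expression filter counts ES3 and ES6 themselves, so markers high only there could pass through them. FOXJ1 was 121 CPM in ES6 and at most 0.302 CPM in any other library. CD86, at a mean FPKM of 0.52, was 15.6 CPM in ES3.

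**Figure D3:**
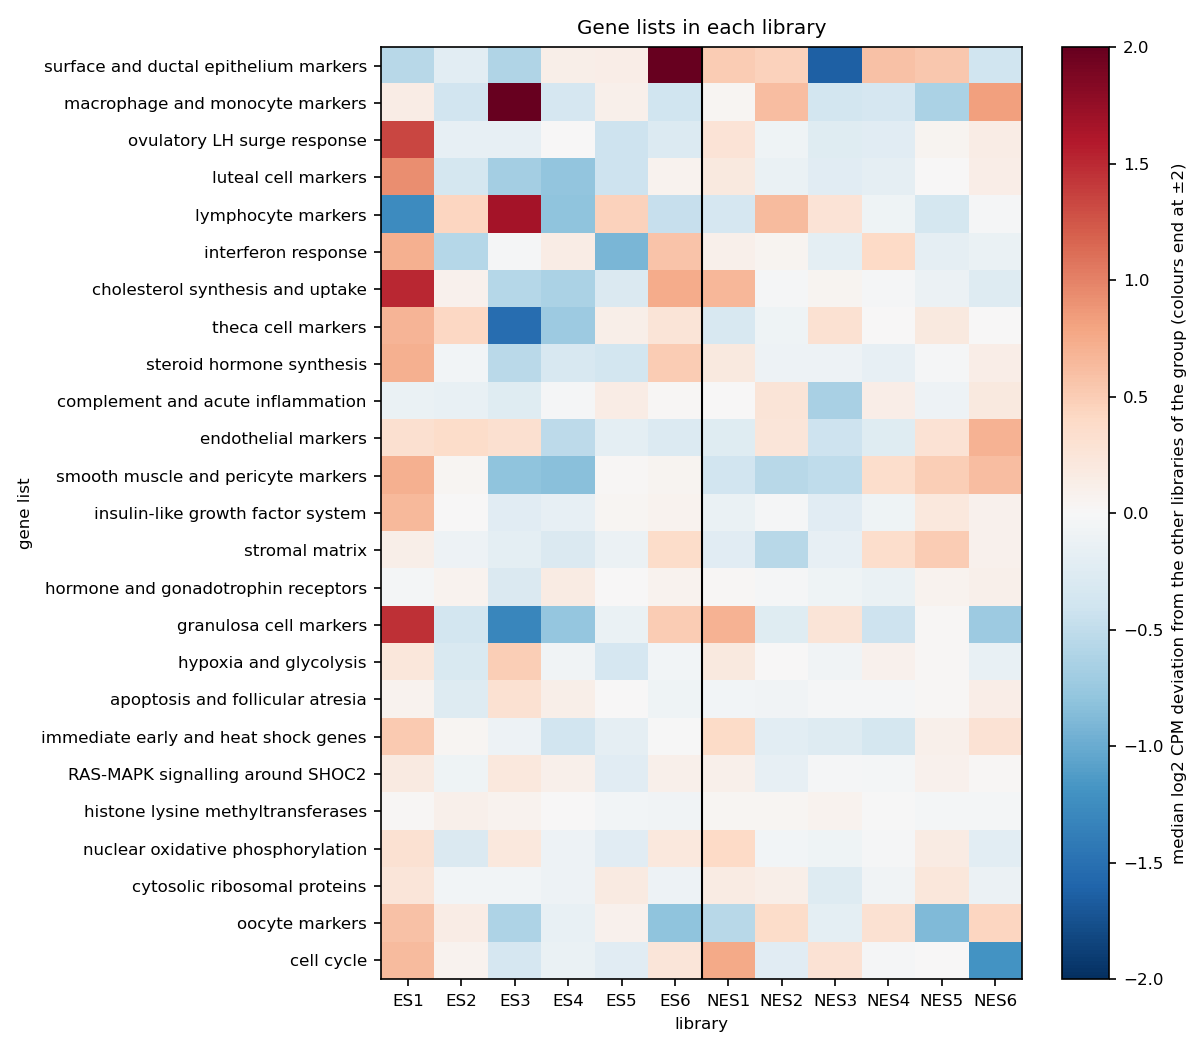
Median log2 CPM deviation of 25 gene lists in each library (columns) from the median of the other libraries of its group, with red higher, blue lower and colours ending at ±2. ES3 stands out for macrophage markers (3.29), ES6 for epithelial markers (2.96) and ES1 for cholesterol synthesis (1.51), granulosa (1.45) and ovulatory response genes (1.33).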

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

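Values of the named genes and the depth measures were searched for a library far from the other 5 of its group, on the log2 scale for genes, with the gap to the nearest library set against the range of the group. Of 176 values tested, 22 stood out and chance gives 8.8. ES3 held 9 of them. The tests of granulosa share, luteal tissue and shallower sequencing below were chosen only after the results were seen, as were the spreads that list medians are held against.

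ES3 was highest of the ES libraries for LYZ (417 CPM, others 1.25 to 4.05), CD86 (15.6 CPM), LAPTM5 (308.5 CPM, others 29.8 to 46.8), TYROBP (36.1 CPM), FN1 (6457 CPM, others 179 to 451) and POSTN (222 CPM), and lowest for INHA (10.7 CPM, others 409 to 3553), IHH (0.742 CPM) and ESR2 (0.695 CPM). Shallower sequencing is argued against, since its total of 64651181 counts lies above the lowest other ES total of 60153877. More luteal tissue stays open, since the luteal markers went both ways. They had a median log2 deviation of -0.68 from the other ES libraries (percentile 0.01 of 10000 random lists matched on expression). However, 6 of 13 were higher, with an SD of 2.47. HSD3B1 (539.6 CPM) and PTGFR (181 CPM) were highest of all 12 libraries in ES3, while STAR (11.6 CPM) and LHCGR (49.1 CPM) were lowest. Lymphoid or other immune tissue in this sample may contribute. All 8 lymphocyte markers lay above the median of the other ES libraries, by a median of 1.67 (percentile 100). IL7R stood at 11.8 CPM in ES3 and 5.82 CPM in ES2. ZAP70, at 3.43 CPM in ES3, was higher in ES5 (3.61 CPM). CCL5 was 3.41 CPM in ES3, 2.66 CPM in ES2 and 2.53 CPM in ES5. The expression filter that all 8 passed counts ES3 itself, and whether the immune cells belong to the ovary stays open.

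PTGS2 reached 213 CPM in ES4, with 1.35 to 2.76 CPM in the other ES libraries, and FRMD6 reached 111 CPM there, with 38.1 to 54.2 CPM in the others. By the rule fixed beforehand, a low percentile among matched random lists, an ovulatory response of this gilt would be argued against. The other 19 genes of that list lay at a median of -0.13 in ES4 (percentile 7.46). That median lay within the random range of -0.18 to 0.20, a condition not in that rule, so the question stays open. Of these genes 9 of 19 were higher, with an SD of 1.74. A stress response to tissue handling is argued against for the list as a set, by the rule fixed beforehand. Immediate early and heat shock genes lay at a median of -0.39 (percentile 0), below the range of -0.15 to 0.17 of matched random lists. Of these genes 7 of 23 were higher, and their SD of 0.51 is wider than that median. By the spread rule used for luteal tissue, which was chosen later, the question would stay open.

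The cell cycle genes lay lower in ES at a median log2 difference of -1.39. Chance is argued against for the number of called loci of all kinds. Of 100 divisions of the 12 libraries, only 1, the real one, gave as many (193 loci, highest other 1). These 100 were drawn from 462 possible divisions and took no account of which gilts are sisters. With the replicate number as a block, edgeR called 0 loci. A single library is argued against, since the median stayed at -1.196 or lower without each library in turn. Camera also called the list in all 12 fits, which adds little, since it called lists in all 99 other divisions too. With all libraries and an estimated correlation, camera's adjusted p for the list was 0.0894. The count of called loci, in contrast, depends on single libraries. A lower share of granulosa cells stays open, since the granulosa markers had a median of 0.1644 (-0.17 with limma on TPM) but went both ways with an SD of 1.337, with 5 of 19 below a bound of -0.69 set from the cell cycle median, and camera placed the list lower (adjusted p = 0.0489, 0.487 as adjusted p with an estimated correlation, called in 8 of 26 alternative fits). Fewer dividing cells within the follicles of ES ovaries stay open too, untested, since the estrus state is what the groups differ in by design. For the number of called lists chance cannot be excluded, since 6 of 100 divisions gave as many (15 lists, highest other 17) and all 99 others called at least 3 lists.

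The remaining values were as follows. In ES1, BMPR1B stood at 4512 CPM (others 136 to 505) and AREG at 73.6 CPM (others 0.111 to 1.10). FOXJ1 stood at 121 CPM in ES6, with 0.242 CPM or less in the other ES libraries, and the origin of the epithelial transcripts in ES6, from the ovary or from tissue next to it, was not tested. NES6 was lowest for HHIP (18.8 CPM) and highest for EMCN (71.3 CPM). NES1 was highest for SCARB1 (304 CPM), had 0 counts of CD4, and had the lowest share of counts in unnamed loci (7.99%). NES3 was lowest for CDH1 (0.707 CPM) and RPL14 (66.2 CPM) and had 0 counts of CLDN4.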

How the results depend on the processing

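The DESeq2, robust edgeR and joint ES3 and ES6 settings were chosen after the data were seen. All 193 called loci kept their direction in every fit that tested them (155 of them with a filter of 1). They were chosen from the same libraries that these fits use, so this decides little. The number of called loci did not hold. It was 0 with the replicate block and with the rank-sum test, 28 with no filter, 1 without ES3 and ES6 together, 1065 with DESeq2, 337 with limma (334 and 319 at pseudocounts of 0.1 and 1), 60 with limma after median-of-ratios scaling, 82 with limma and the replicate block, 314 with robust and 386 with weighted limma, and 0 to 415 with a library left out. It stayed within 1.5 times with median-of-ratios scaling, a filter of 1, the robust fit, limma on TPM and quantile scaling. The unfiltered fit tested more loci. The rank-sum test gives no p below 0.0022 with 6 against 6 libraries. After adjustment over 20421 loci a call would need very many loci at that floor, so its 0 calls decide little. For the other settings the cause was not tested. In the edgeR block fit and the rank-sum test, 2708 and 2835 loci had an unadjusted p under 0.05. The labels do not tie replicate numbers to litters, and the data left it open. Correlations of same-numbered libraries ran from -0.032 to 0.24, 2 of 6 over 0.1, and 3 ES and 3 NES libraries correlated best with their own number. ES1, ES2 and ES5 correlated at 0.24, 0.099 and 0.22 with their own number. With any other NES library they reached at most -0.0028, 0.0074 and 0.037. ES3, ES4 and ES6 each correlated better with an NES library of another number. The median log2 difference of all loci was 0.043 in the edgeR fit and -0.11 with limma on TPM. The number of called lists was 0 with an estimated correlation and 3 with fry. In the other 25 fits it stayed within 1.5 times of 15, and it was 12 to 16 with a library left out. With the replicate block in edgeR the granulosa median turned to -0.056 and the theca median was 0.12, while the cell cycle median was -1.34. ASH1L and SHOC2 passed no test. ASH1L turned to 0.051 with median-of-ratios scaling and 0.063 with edgeR and ran from -0.086 to 0.0045 with a library left out. SHOC2 turned to -0.017 on TPM and ran from -0.037 to 0.085. Of 2386 values of 83 other named genes, 2033 kept direction and side of the threshold, 287 lost and 48 gained the call, and 18 turned. CYP17A1 was -0.034 with limma on TPM. LHCGR was -0.047 with the replicate block and, with limma, -0.11 (also with the replicate block, robust and rank-sum), -0.17 and -0.055 at pseudocounts of 0.1 and 1, -0.22 on TPM, -0.040 with quantile and -0.032 with median-of-ratios scaling, and ran from -0.18 to 0.77 with a library left out. LYZ (-0.52), TYROBP (-0.11) and FOXJ1 (-1.01) turned without ES3 and ES6 together, and ran from -0.26 to 4.93, -0.13 to 2.45 and -1.08 to 7.18. A count of 0 allows up to 0.0435 to 0.0516 CPM at this depth.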

Other observations

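The tests of histone loci and of GO terms and the genes of single libraries were chosen only after the results were seen. Histone genes, most of which are transcribed while DNA replicates, lay lower in ES beside the cell cycle list. Of 38 tested loci described as histone genes, all 38 had lower means in ES, 16 fell and 0 rose, with a median log2 difference of -1.24 (fry p = 7.10e-04; camera p = 0.00472 with an estimated correlation). They include 29 loci on chromosome 7 between 20465129 and 21633898. A histone H4 locus (MSTRG.20500) averaged 43.5 CPM in ES and 127 CPM in NES (log2 -1.55, adjusted p = 0.0345), and a histone H2A type 1 locus (MSTRG.20479) fell from 6.78 to 1.95 CPM (log2 -1.80). Near-identical copies share reads, so single loci are less certain than the group.

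GO terms of the table's own annotation were tested over 1868 terms and 9161 annotated genes. Among the 110 annotated genes called lower, 48 terms were enriched (Fisher's exact test, Benjamini-Hochberg). They include chromosome segregation with 12 of 42 genes (adjusted p = 3.72e-11), the centromeric region of chromosomes with 11 of 24 (1.84e-12) and DNA repair with 8 of 113 (0.00469). Among the 13 annotated genes called higher, 0 terms were enriched. The term for smoothened signalling, the hedgehog pathway, held 4 called genes of 46 (adjusted p = 0.0740) and had a median log2 difference of -0.069 (camera lower, adjusted p = 0.00486; fry 0.172). With camera 194 terms passed and with fry 0.

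Single ES libraries carried groups of genes at 10 CPM or more and at least 10 times their level in every other library, while no NES library had any. ES3 had 36, among them CTSD (2423 CPM), CLU (2034 CPM), APOE (1437 CPM) and TREM2 (33.2 CPM), genes of lysosomes, lipid transport and macrophages. ES6 had 29, among them the ciliary genes HYDIN (202 CPM, 3.50 CPM in the next library), DNAH11 (81.9 CPM) and SPAG6 (15.3 CPM), and the secretory epithelial genes DMBT1 (185 CPM) and SLPI (77.7 CPM). ES1 had 13, with SDC4 at 1512 CPM and IL11 at 31.2 CPM, and its PGR stood at 2135 CPM where the other ES libraries had 37.2 to 349.7 CPM. ES4 had 9, with BSP1 at 67.2 CPM, DKK1 at 27.3 CPM and RHCG at 25.3 CPM beside PTGS2. ES5 had 0.

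The steroid genes were spread unevenly over the ES ovaries. STAR reached 728 CPM in ES6 and 655 CPM in ES1 and stood at 11.6 CPM in ES3. CYP17A1 was 635 CPM in ES1, 577 CPM in ES6, 5.01 CPM in ES4 and 0.474 CPM in ES3, with 31.9 to 156 CPM in NES. HSD3B1 was highest in ES3 (539.6 CPM), and CYP11A1 in ES1 (1515 CPM). CYP19A1 was 1039.7 CPM in ES6 and 466 CPM in ES1, and 14.4 and 12.3 CPM in ES3 and ES4.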
